A study of Mus musculus with 6 samples.

How the data were processed

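Colon tissue from C57BL/6 mice was collected 6 h after treatment with phosphate-buffered saline (PBS), wild-type interleukin-22 (WT IL-22) or 22-B3, an engineered variant of the cytokine, the proteins at 200 µg per mouse, per the labels. The set held 6 libraries in 3 groups of 2. Per the labels' protocols, frozen tissue was ground, RNA was isolated on columns, and libraries were made with an NEBNext Ultra II kit from 0.2 µg RNA after mRNA enrichment. The submitters' processing notes name STAR 2.5 and the mouse genome build mm10. The read counter, the annotation release and the strand setting were not given in the sources used here, so reads of overlapping or antisense genes cannot be separated, and genes with near-identical copies are given as uncertain.

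The deposited count table holds whole-number read counts per gene for 35275 genes, one column per library, with no normalization, per the file headers and the values. The deposited FPKM table was computed by the authors from those counts: each FPKM value equalled the count scaled by the gene length and the column total, with a largest relative deviation of 5e-12. Gene symbols, coordinates and lengths are those of the deposited tables. Column totals ranged from 17428528 to 22081904 counts. The labels do not state that the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical in part.

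The count table was analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups (15628 genes), libraries were scaled by TMM, and 1 mean per group was fitted to all 6 libraries. Each pair of groups was compared with edgeR's quasi-likelihood test with robust dispersion and Benjamini-Hochberg adjustment within the comparison, called edgeR adjusted p below, and a gene passed at an adjusted p under 0.05. Levels are TMM-normalized CPM with the SD over 2 libraries. Standard errors were derived from the fitted log2 change and its F statistic, and intervals are at 95%. A group with a count of 0 in both libraries was set to a floor of 3 counts over both libraries. The intervals rest on the fitted spread between libraries. Floors based on counts cover counting error only, since the libraries had no molecular identifiers.

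For 46 gene lists of functions, cell types and regions, camera with an inter-gene correlation of 0.01 asked whether a list moved relative to the other genes, with Benjamini-Hochberg adjustment over the 45 lists with enough tested genes (camera adjusted p). The correlation estimated per list and fry, limma's self-contained set test, were run beside it (limma 3.58.1). With an estimated correlation 0 lists passed in each of the 3 comparisons, against 3, 2 and 3 lists at an unadjusted p under 0.05 for WT IL-22 against PBS, 22-B3 against PBS and 22-B3 against WT IL-22. fry passed 4, 1 and 0 lists in that order, and 14, 10 and 4 at an unadjusted p under 0.05.

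The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. By that rule the text names, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among genes that passed, whose groups did not overlap, and whose mean count in the higher group was at least 50, leaving out predicted genes without a proper symbol. It also names genes of a panel of 35 whatever their result, and members of a list among the 4 with the smallest p. The results of 2 genes and 1 gene list are not reported here. Of the alternatives, 22 were run, among them DESeq2 1.42.0, limma-voom, limma on log2 FPKM, other scalings and filters, a block for the replicate number, and each library left out in turn. Of these 22, 3 were added after the data had been seen: the PBS libraries summed into 1 library, immunoglobulin variable genes removed, and Yam1, Lars2 and Gm26917 removed.

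The share of the WT IL-22 change kept by 22-B3 was the least-squares slope through the origin, and the median ratio, of the log2 changes. For a gene list the share was instead the list's mean log2 change with 22-B3 over its mean log2 change with WT IL-22. Because both treatments were set against the same PBS libraries, unchanged groups were simulated in 50 draws, and in 10 draws for the share. Each draw made new PBS libraries around the observed PBS means, which both simulated comparisons shared. Each gene was drawn on its own, so genes that shift together in 1 animal are not represented. The test was also tested on simulated data with known changes over 15368 genes. All libraries were drawn there as independent, with the dispersion of the main fit, which includes the PBS pair. Changes were put only in genes with a mean above 1 CPM. The test called 53% of 2-fold and 94% of 4-fold changes and 0.073% of unchanged genes for WT IL-22 against PBS. For 22-B3 against PBS it called 56% of 2-fold changes and 4% of log2 changes of 0.5, and for 22-B3 against WT IL-22 49% and 0%.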

Results

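RNA from mouse colon was sequenced 6 h after PBS, WT IL-22 or 22-B3, with 2 libraries per group (n = 2 for every mean below). IL-22 acts on epithelial cells through a receptor made of Il22ra1 and Il10rb and signals mainly through STAT3. Total counts were 19329695 and 19744956 in the PBS libraries, 20740041 and 22081904 with WT IL-22, and 17428528 and 19022869 with 22-B3. Mitochondrially encoded genes took 1.85% to 2.35% of the counts. The non-coding RNA Yam1, among the genes that differed most within the PBS pair, had 69601 and 395634 counts there, 47810 and 40790 with WT IL-22, and 58063 and 237528 with 22-B3.

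The PBS libraries were closer to each other than any other pair. Immunoglobulin variable genes are the antibody gene segments that differ between B cell clones. On log2 counts (plus 1) they correlated at r = 0.963 across 79 genes in the PBS pair, against -0.147 to 0.165 in the other 14 pairs of libraries. Genes with a summed count of at least 50 in a pair were used, so the set differed by pair. Genes are not independent replicates. The biological coefficient of variation was 5.47% within the PBS pair, 17.1% within the WT IL-22 pair and 22% within the 22-B3 pair. The PBS libraries still differed by more than sampling noise, with 24.7% of genes beyond the 5% point of chi-square, and were kept as 2 replicates. The totals of changed genes below, and the members of called lists that passed, are therefore also given with the PBS libraries summed into 1. By the same chi-square measure, 61.85% of genes differed within the 22-B3 pair and 55.6% within the WT IL-22 pair. 22-B3 replicate 1 differed from the WT IL-22 libraries in 50.1% and 53.7%, and from the PBS libraries in 66.3% and 66.9%. 22-B3 replicate 2 differed from the PBS libraries in 52.9% and 54.3%, and from the WT IL-22 libraries in 67.2% and 57.8%. Means over the 22-B3 pair thus join a library nearer to WT IL-22 and another nearer to PBS.

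**Figure D1:**
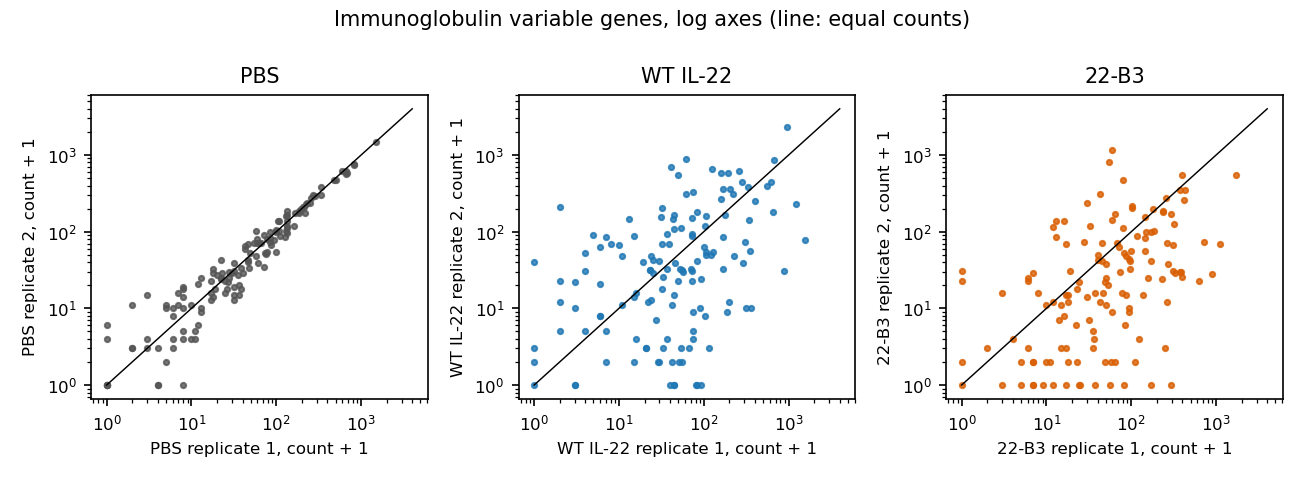
Counts (plus 1, log axes) of immunoglobulin variable genes in replicate 1 (x axis) and replicate 2 (y axis) of each group, 1 point per gene, with a line of equal counts. The PBS points lie along the line (r = 0.963), while the median absolute log2 ratio between replicates was 1.73 for WT IL-22 and 2.03 for 22-B3.

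The first comparison asked what WT IL-22 changed in the colon. Socs3, the feedback inhibitor of STAT3 signalling (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047, mm10), rose from 7.44 ± 0.516 CPM with PBS to 251 ± 4.21 CPM, a log2 change of 5.07 (SE 0.184, edgeR adjusted p = 6.6e-06). AI747448, a member of the calcium-activated chloride channel regulator family (ENSMUSG00000074195, chromosome 3, 144910921 to 144932529), rose from 2.09 ± 0.0904 to 188 ± 15.7 CPM, a log2 change of 6.48 (SE 0.185, edgeR adjusted p = 1.65e-06); reads of its paralogs could be split with it, so its value is uncertain. The lysophospholipid transporter Mfsd2a rose by 3.83, Trim15 by 3.53 and the sugar transporter Slc5a9 by 3.52 on the log2 scale (edgeR adjusted p = 0.000205, 0.000205 and 0.000323), and Dnah17 rose by 4.86 (edgeR adjusted p = 0.00217). The protease Prss27 had 0 and 1 counts in the PBS libraries and a mean of 2.82 CPM with WT IL-22. Cyp2c68 and Cyp2c69, neighbouring cytochrome P450 paralogs that are uncertain for the same reason, fell, with log2 changes of -3.15 and -3.68 (edgeR adjusted p = 0.000238 and 0.000664), and the mast cell protease Mcpt2 fell by 2.97 (edgeR adjusted p = 0.00613). Immunoglobulin variable genes made up 3 of the 10 named rises and 7 of the 10 named falls. Igkv6-13, for example, had 30.7 and 31.7 CPM with PBS and 0.0934 and 0 CPM with WT IL-22.

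In all, 1547 genes rose and 1054 fell among 15628 tested. With the PBS libraries summed the counts were 129 and 29, and 32 of the 122 named genes that passed still passed, among them Socs3 (edgeR adjusted p = 0.000389) and AI747448 (edgeR adjusted p = 0.000206). Leaving out any 1 library moved a count by more than 1.5 times: the counts were 120 and 29 without PBS replicate 1, 117 and 28 without PBS replicate 2, 333 and 126 without WT IL-22 replicate 1, 1014 and 645 without WT IL-22 replicate 2, 2589 and 2454 without 22-B3 replicate 1, and 2782 and 2220 without 22-B3 replicate 2. Upper-quartile scaling gave 1090 rises and 1566 falls, with the median of all genes at -0.13 in place of -0.01.

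Genes of cell division rose together with WT IL-22. Of 32 cell cycle genes, 21 rose over all genes tested and, adjusted over the list alone, 24 rose and 1 fell, with a median log2 change of 0.89 (camera adjusted p = 2.6e-22; adjusted p = 0.0839 with an estimated correlation). The replication licensing genes led the list: Mcm5 rose from 40.9 ± 0.705 to 151 ± 5.61 CPM, a log2 change of 1.89 (edgeR adjusted p = 0.000286), Mcm3 by 2.30, Mcm6 by 2.14 and Mcm7 by 1.91. Among 14 genes of the STAT3 feedback list, 8 rose and 1 fell, both over all genes tested and adjusted over the list alone (median 0.65, camera adjusted p = 2.71e-07; adjusted p = 0.218 with an estimated correlation). Beside Socs3, these included Bcl3 at 1.73, Stat3 at 1.16 and Il4ra at 0.84 on the log2 scale (edgeR adjusted p = 0.00219, 0.00812 and 0.00708). Of the interferon-induced genes, Oasl2 rose by 2.41 and the guanylate-binding protein gene Gbp2 by 1.80 (edgeR adjusted p = 0.00058 and 0.00162).

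Acute phase, secretory and glycosylation genes were also higher with WT IL-22. Of 9 acute phase genes 4 rose, and 4 adjusted over the list alone (camera adjusted p = 2.23e-05; adjusted p = 0.581 with an estimated correlation), with Lbp, the lipopolysaccharide-binding protein, going from 6.12 ± 0.346 to 45.5 ± 8.18 CPM and Lrg1 rising by 2.25 on the log2 scale (edgeR adjusted p = 0.000205 and 0.000272). Saa2 is among the 4 but had 1 count in total in the PBS libraries and 0.946 CPM with WT IL-22, and its reads could be shared with Saa1. Of 25 genes of ER stress and secretory chaperones 10 rose and 1 fell, against 12 and 2 adjusted over the list alone (camera adjusted p = 9.96e-05; adjusted p = 0.547 with an estimated correlation). They included the amino acid synthesis gene Asns at 1.47, Hyou1 at 1.19 and Hsp90b1 at 1.02 on the log2 scale (edgeR adjusted p = 0.00248, 0.00305 and 0.00613). Of 18 cholesterol synthesis genes 7 rose, 12 adjusted over the list alone (camera adjusted p = 0.000237; adjusted p = 0.768 with an estimated correlation), with Sqle at 0.89 (edgeR adjusted p = 0.0187). Of 19 fucosylation and glycosylation genes 4 rose, 7 adjusted over the list alone (camera adjusted p = 0.00164; adjusted p = 0.581 with an estimated correlation). Fut2, which adds terminal fucose to epithelial glycans, rose from 136 ± 4.51 to 683 ± 64 CPM (log2 change 2.33, edgeR adjusted p = 0.00041), and B3galt5 and B4galnt2 rose by 1.45 and 1.21 (edgeR adjusted p = 0.00343 and 0.00876).

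Lists of smooth muscle, antigen presentation, macrophages and glucocorticoid response were lower with WT IL-22. Of 12 smooth muscle genes 5 fell, 8 adjusted over the list alone (median -0.66, camera adjusted p = 2e-04; adjusted p = 0.768 with an estimated correlation), such as Tagln at -1.17 and Smtn at -0.62 (edgeR adjusted p = 0.0256 and 0.0237). The list mean relative to PBS was -0.85 in WT IL-22 replicate 1 and -0.43 in replicate 2. Of 7 MHC class II genes 4 fell, 5 adjusted over the list alone (camera adjusted p = 0.00471; adjusted p = 0.818 with an estimated correlation), with H2-Aa at -0.86 (edgeR adjusted p = 0.0204). The list stood at -0.92 and -0.43 in the WT IL-22 libraries, relative to PBS, beside -0.67 and -0.44 for 11 B and plasma cell genes. Of these 1 fell over all genes tested, edgeR called 0 adjusted over the list alone (4 at an unadjusted p under 0.05) and DESeq2 called 2 lower (camera adjusted p = 0.107); without 22-B3 replicate 1, 5 fell (camera adjusted p = 0.0394), without replicate 2, 4 fell (0.0323), and over the alternatives the adjusted p ran from 0.0323 to 0.917. Of 10 macrophage genes 4 fell, and 4 adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.818 with an estimated correlation), Lyz2 at -1.21 (edgeR adjusted p = 0.00672) and 3 complement C1q genes. Of 11 glucocorticoid response genes 2 fell, and 2 adjusted over the list alone (camera adjusted p = 0.0038; adjusted p = 0.735 with an estimated correlation), Tsc22d3 at -1.67 and Sgk1 at -1.38 (edgeR adjusted p = 0.00283 and 0.00994). The camera adjusted p of the macrophage list was 0.102 without WT IL-22 replicate 1 and that of the glucocorticoid list 0.104 without WT IL-22 replicate 2.

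Fewer members of these lists passed with the PBS libraries summed: 10 cell cycle, 2 STAT3 feedback, 2 acute phase and 1 fucosylation genes rose and 1 glucocorticoid gene fell. edgeR then called 0 chaperone, cholesterol, smooth muscle, MHC class II and macrophage genes, with 11, 5, 6, 4 and 4 at an unadjusted p under 0.05. The called counts did not differ from these without either PBS library, apart from 9 cell cycle genes without PBS replicate 1. Without WT IL-22 replicate 1, 2 STAT3 feedback, 2 acute phase, 3 chaperone and 1 cholesterol genes rose, 1 macrophage and 4 glucocorticoid genes fell, and edgeR called 0 smooth muscle and MHC class II genes (5 and 4 at an unadjusted p under 0.05). Without WT IL-22 replicate 2, 5 STAT3 feedback, 2 acute phase, 6 chaperone and 3 cholesterol genes rose. Without 22-B3 replicate 1, 9 fucosylation and 14 cholesterol genes rose and 3 chaperone, 8 smooth muscle and 4 glucocorticoid genes fell, and without 22-B3 replicate 2, 10 and 14 rose and 3 chaperone and 8 smooth muscle genes fell.

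Host defence genes moved unevenly. Duox2 and Duoxa2, which form an epithelial peroxide-producing oxidase, rose by 2.20 and 1.58 and Nos2, the inducible nitric oxide synthase, by 2.94 on the log2 scale (edgeR adjusted p = 0.00356, 0.00172 and 0.00706). Muc1 and Muc13, transmembrane mucins, rose by 1.83 and 1.70 (edgeR adjusted p = 0.00119 and 0.00249), while Muc2, the secreted mucin of goblet cells, had a log2 change of 0.26 (edgeR adjusted p = 0.458). The antimicrobial lectin gene Reg3b had 0 counts in both PBS libraries and 1100 and 168 CPM with WT IL-22, at least 8170-fold higher on average, yet the spread between these libraries left it short of the test (edgeR adjusted p = 0.136). Reg3g, its paralog, had 0.462 and 0.312 CPM with PBS and 331 and 49.95 CPM with WT IL-22 (edgeR adjusted p = 0.101), and the reads of the pair are uncertain between them. Of 15 antimicrobial genes 3 rose, Pla2g2a, Slpi and Reg1, and adjusted over the list alone 3 rose and 4 fell (camera adjusted p = 0.675). Reg1 had 0 counts in both PBS libraries and a mean of only 1.13 CPM with WT IL-22. Of 11 chemokine genes 1 rose and 2 fell, and as many adjusted over the list alone (camera adjusted p = 0.34): Cxcl5 at 2.48, Ccl28 at -1.004 and Cxcl16 at -0.925 on the log2 scale (edgeR adjusted p = 0.0406, 0.00691 and 0.0225). With the PBS libraries summed edgeR called 0 antimicrobial and chemokine genes (5 and 3 at an unadjusted p under 0.05). Il22ra1, Il10rb, Il22ra2, Irf1, Lcn2, Retnlb, B3gnt7, Saa1, Saa3, Il1b, Tnf, Il18, Cxcl9, Cxcl10 and Ccl20 did not pass in any of the 3 comparisons, and S100a8, S100a9, Cxcl1, Cxcl2 and Il6 had at most 17 counts in any library and were not tested.

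**Figure D2:**
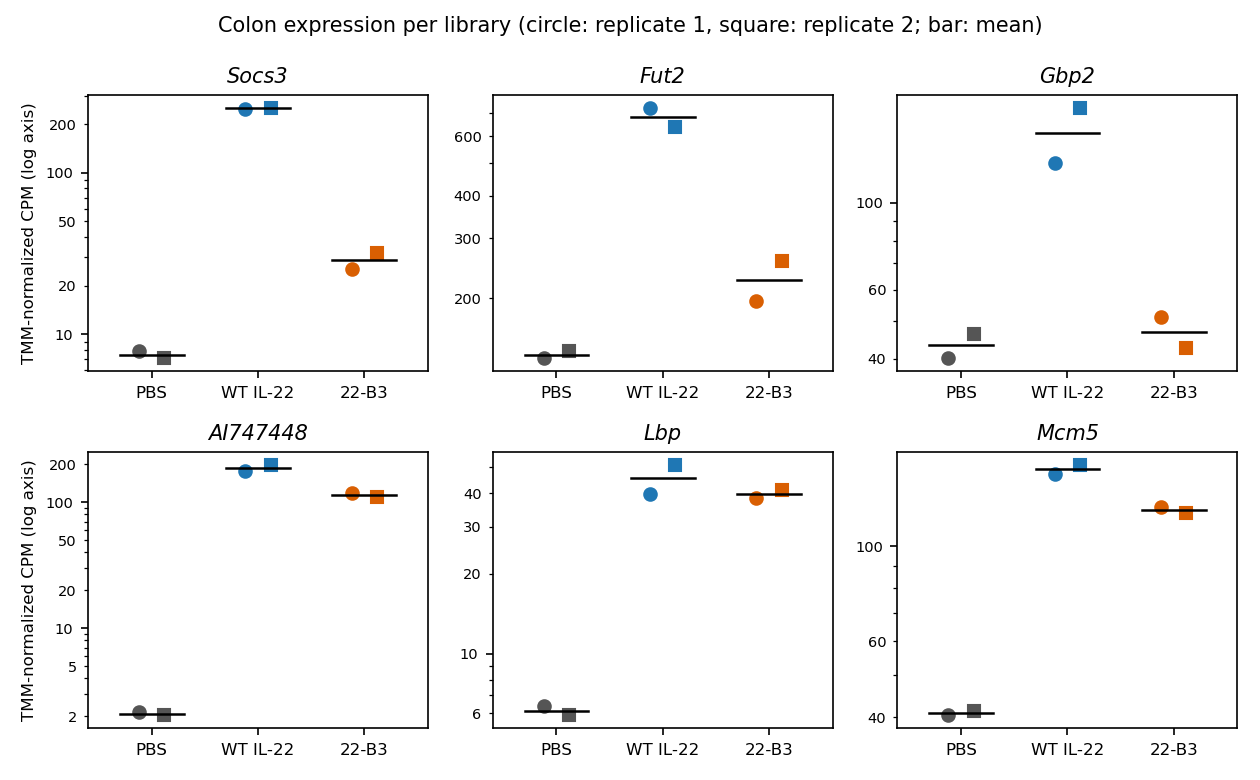
TMM-normalized CPM on log axes for 6 genes in the PBS, WT IL-22 and 22-B3 libraries, with a circle for replicate 1, a square for replicate 2 and a bar for the mean. Socs3, Fut2 and Gbp2 lie nearer to PBS with 22-B3 (28.7, 227 and 46.9 CPM), while AI747448, Lbp and Mcm5 lie nearer to WT IL-22 (114, 39.8 and 121 CPM).

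The second comparison asked what 22-B3 changed at the same dose and time. AI747448, uncertain between paralogs as above, rose to 114 ± 5.84 CPM, a log2 change of 5.76 (SE 0.182, edgeR adjusted p = 3.88e-06), and Lbp rose to 39.8 ± 2.09 CPM, a log2 change of 2.70 (SE 0.186, edgeR adjusted p = 0.00106). Slc5a9 rose by 2.90, Cpn2 by 2.43 and Syt12 by 2.39 on the log2 scale (edgeR adjusted p = 0.00186, 0.00513 and 0.00962). Socs3 rose to 28.7 ± 4.75 CPM, a log2 change of 1.94 (SE 0.17, edgeR adjusted p = 0.00186). Mcpt2, Cyp2c69 and the non-coding RNA Meg3 fell, with log2 changes of -3.50, -1.77 and -1.54 (edgeR adjusted p = 0.0161, 0.0267 and 0.0291). Immunoglobulin variable genes were 5 of the 10 named rises and 7 of the 10 named falls. Ighv1-39, for example, had 34.1 and 32.5 CPM with PBS and 0.449 and 0 CPM with 22-B3.

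In all, 148 genes rose and 24 fell, against 2 and 3 with the PBS libraries summed; of the 34 named genes that passed, AI747448, Lbp, Igkv6-13, Igkv10-94 and Ighv1-39 still passed. The counts were 7 and 3 without PBS replicate 1, 2 and 3 without PBS replicate 2, 100 and 37 without WT IL-22 replicate 1, 215 and 62 without 22-B3 replicate 1, and 1391 and 858 without 22-B3 replicate 2.

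Cell cycle genes rose with 22-B3 as well, 11 of 32 over all genes tested and 20 adjusted over the list alone (median 0.62, camera adjusted p = 1.93e-26; adjusted p = 0.0601 with an estimated correlation). Mcm5 reached 121 ± 3.03 CPM, a log2 change of 1.57, and Mcm3 and Mcm6 rose by 1.85 and 1.82 (edgeR adjusted p = 0.00186, 0.00215 and 0.00186). Of 18 cholesterol synthesis genes 1 rose over all genes tested and 12 adjusted over the list alone (median 0.49, camera adjusted p = 3.62e-07; adjusted p = 0.697 with an estimated correlation). Of 9 acute phase genes 2 rose, Lbp and Lrg1 (log2 change 1.47, edgeR adjusted p = 0.00427), and 4 adjusted over the list alone (camera adjusted p = 6.43e-06; adjusted p = 0.697 with an estimated correlation and 0.109 with fry). Over the other alternatives its camera adjusted p ran from 9.48e-07 to 0.208, and the call was lost with no low-count filter, at 0.208, and on log2 FPKM with no filter, at 0.18. Of 25 ER stress and chaperone genes 2 rose, Hsp90b1 at 0.89 and Creld2 at 0.79 (edgeR adjusted p = 0.0393 and 0.0417), and 10 adjusted over the list alone (camera adjusted p = 4.97e-05; adjusted p = 0.697 with an estimated correlation). With the PBS libraries summed edgeR called 1 acute phase gene, Lbp, and 0 cell cycle, STAT3 feedback, cholesterol and chaperone genes (18, 3, 4 and 8 at an unadjusted p under 0.05), and as many without either PBS library. Without either WT IL-22 library it called 0 cholesterol and chaperone genes (11 and 13 at an unadjusted p under 0.05). Without 22-B3 replicate 1, 7 chaperone genes rose, and without 22-B3 replicate 2, 9 rose and 2 fell, with 14 cholesterol and 3 STAT3 feedback genes rising.

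The remaining lists did not pass or lost their call without 1 library. Of 14 STAT3 feedback genes 1 rose, Socs3, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.101). Gbp2 stood at 46.9 ± 6.05 CPM against 43.3 ± 4.46 CPM with PBS (edgeR adjusted p = 0.77). Adjusted over the list alone 4 of 7 MHC class II genes and 3 of 11 B and plasma cell genes fell (camera adjusted p = 0.000139 and 0.000697; adjusted p = 0.708 and 0.771 with an estimated correlation); without 22-B3 replicate 2 their camera adjusted p was 0.0802 and 0.311. The B and plasma cell list stood at -0.24 in 22-B3 replicate 1 and -1.51 in replicate 2, relative to PBS. Another 8 lists passed at camera adjusted p from 0.0144 to 0.0479 (adjusted p = 0.697 to 0.771 with an estimated correlation): neutrophil, tight junction and fucosylation genes upward, and smooth muscle, adipocyte, macrophage, goblet cell and fibroblast genes downward. Without 22-B3 replicate 2 the camera adjusted p was 0.125 for fucosylation, 0.0763 for neutrophil, 0.504 for adipocyte, 0.256 for macrophage, 0.0948 for tight junction and 0.279 for fibroblast genes. Without 22-B3 replicate 1 it was 0.0619 for smooth muscle and 0.072 for goblet cell genes. Without PBS replicate 1 it was 0.0508 for neutrophil, 0.0571 for goblet cell, 0.0728 for tight junction and 0.0508 for fibroblast genes, and without PBS replicate 2 it was 0.0643 for macrophage genes. Duoxa2, Muc1 and Muc13 rose by 1.05, 1.42 and 1.31 (edgeR adjusted p = 0.0304, 0.0112 and 0.0258), and Ly6g, uncertain within its gene family, by 1.59 (edgeR adjusted p = 0.00369). Reg3b had 26.5 and 364 CPM, at least 2520-fold above PBS on average (edgeR adjusted p = 0.296).

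The third comparison tested the difference between the proteins directly. The PBS libraries entered it only through the gene filter, the scaling and the shared estimate of spread, which the close PBS pair helps to set. Fitted on the 4 treated libraries alone, 4 of the 15 named genes that passed still passed and 11 did not. Socs3 was lower with 22-B3 than with WT IL-22 by a log2 change of -3.13 (SE 0.165, 95% interval -3.50 to -2.75, edgeR adjusted p = 0.000327), and Mfsd2a by -2.81 (edgeR adjusted p = 0.00457). Fut2 stood at 227 ± 42.7 against 683 ± 64 CPM, a log2 change of -1.59 (SE 0.181, edgeR adjusted p = 0.023). The interferon-induced genes Gbp2, Oasl2 and Ifit1 were lower by -1.68, -1.51 and -1.36 (edgeR adjusted p = 0.023, 0.0398 and 0.029), as were Trim15 at -1.97, the sulfotransferase gene Chst4 at -1.36 and the kinase gene Ptk6 at -1.15 (edgeR adjusted p = 0.0188, 0.029 and 0.0312). Higher with 22-B3 were Cyp2c68 at 1.91, Fxyd4, a regulator of the sodium pump, at 1.57, and Sycn at 1.36 (edgeR adjusted p = 0.0188, 0.0223 and 0.049). Immunoglobulin variable genes gave 2 of the 5 named rises and 1 of the 10 named falls. Ighv1-54 had 13.1 and 10.2 CPM with 22-B3 and 0.0934 and 0 CPM with WT IL-22.

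In all, 5 genes were higher and 11 lower, against 2 and 2 with the PBS libraries summed, when Socs3, Mfsd2a, Ighv1-54 and Igkv2-109 were called. The counts were 2 and 2 without either PBS library, 2 and 6 without WT IL-22 replicate 1, 4 and 6 without WT IL-22 replicate 2, 435 and 201 without 22-B3 replicate 1, and 46 and 48 without 22-B3 replicate 2.

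As a group, the STAT3 feedback genes were lower with 22-B3, 1 of 14 over all genes tested and 6 adjusted over the list alone (median -0.41, camera adjusted p = 1.64e-15; adjusted p = 0.156 with an estimated correlation). Over all genes tested 1 was lower with the PBS libraries summed, 2 without WT IL-22 replicate 2 and 6 without 22-B3 replicate 1. The cell cycle list had a median of -0.27 (camera adjusted p = 7.92e-05; adjusted p = 0.388 with an estimated correlation), with 0 of 32 genes past edgeR's test or DESeq2's and 7 at an unadjusted p under 0.05. Of 6 distal colon genes, 2 were higher adjusted over the list alone (median 0.87, camera adjusted p = 7.92e-05; adjusted p = 0.759 with an estimated correlation), and the camera adjusted p was 0.228 without 22-B3 replicate 1; the list stood at -0.88 and -0.31 in the WT IL-22 libraries and 0.61 and -0.16 in the 22-B3 libraries. Another 6 lists passed at camera adjusted p from 0.00136 to 0.0345 (adjusted p = 0.759 to 0.761 with an estimated correlation), smooth muscle, glucocorticoid and chemokine genes higher and fucosylation, enteric neuron and tuft cell genes lower. Without WT IL-22 replicate 1 the camera adjusted p was 0.258 for smooth muscle, 0.0702 for fucosylation, 0.555 for neuron, 0.258 for chemokine and 0.163 for tuft cell genes, and without WT IL-22 replicate 2 it was 0.291 for glucocorticoid genes. Without 22-B3 replicate 1 it was 0.0671 for fucosylation, neuron and tuft cell genes and 0.692 for chemokine genes, and without 22-B3 replicate 2 it was 0.0552 for smooth muscle, 0.154 for neuron and 0.269 for tuft cell genes. Among genes that did not pass, the interval for Lbp, -0.57 to 0.19 on the log2 scale, left both directions open (edgeR adjusted p = 0.726). The intervals for Mcm5, -0.61 to -0.02, and AI747448, -1.03 to -0.41, lay wholly on the side of a lower level with 22-B3. They are not adjusted for the number of genes tested (edgeR adjusted p = 0.488 and 0.121).

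**Figure D3:**
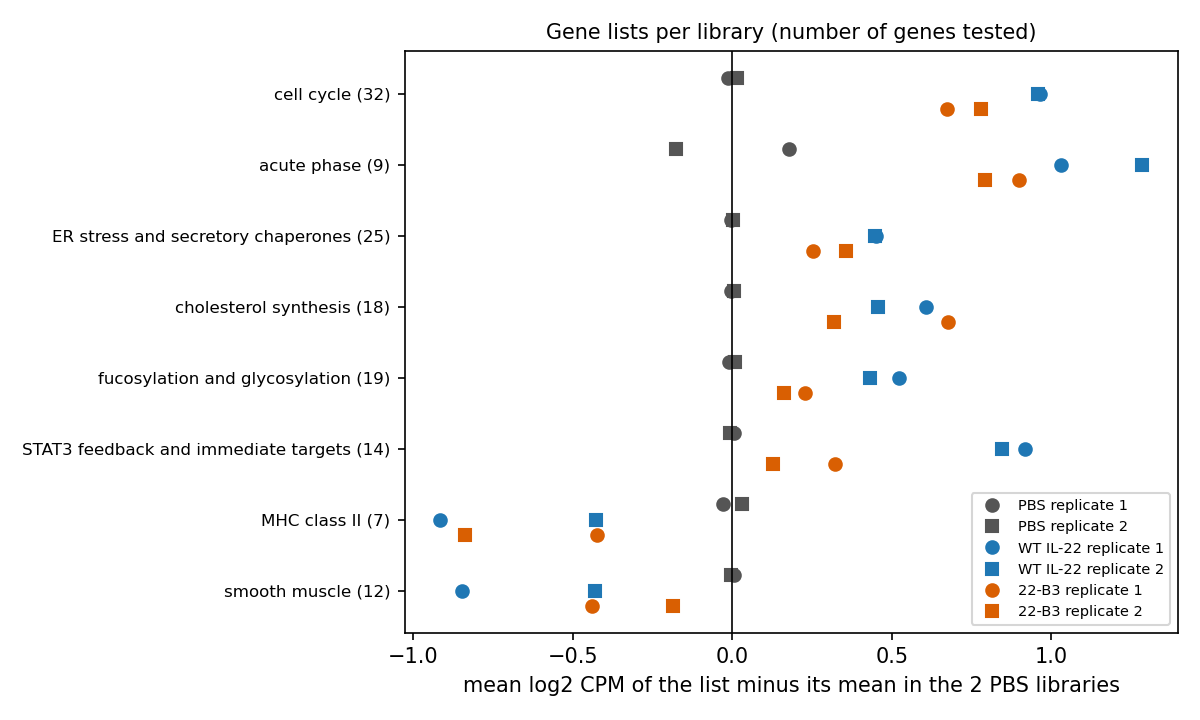
Mean log2 CPM of 8 gene lists in each of the 6 libraries, minus the list's mean in the PBS libraries (x axis), 1 row per list with the number of genes tested; circles are replicate 1 and squares replicate 2. The cell cycle list stands at 0.67 and 0.78 with 22-B3 and 0.96 in both WT IL-22 libraries.

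The size of the 22-B3 change was set against that of WT IL-22. Over the 2601 genes that passed for WT IL-22, the slope was 58.4% and the median ratio 60.0%. From 22-B3 replicate 1 alone the slope was 64.1% and the median ratio 74.4%, and from replicate 2 alone 53.1% and 46.8%. With genes chosen anew without 22-B3 replicate 1 the median ratio was 39.4%, and without replicate 2 it was 81.2%. With genes chosen on libraries not used for the ratio the slope was 59.3% and 59.0%, and the median ratio 53.6% and 66.6%, which is no independent check if both PBS libraries came from 1 animal. Both changes are set against the same PBS libraries. Groups were simulated against shared PBS libraries drawn anew, with WT IL-22 at its observed means and 22-B3 unchanged. They gave a mean slope of 9.84% and median ratio of 10%, or 18% and 19% with 1 PBS animal. With both treatments unchanged the 2601 largest simulated WT IL-22 changes gave 51.8% and 50.5%, or 66.6% and 66.3% with 1 PBS animal, so the share alone does not show a response to 22-B3. The share was also taken per list, as the ratio of list means, with no test of a difference between lists. Cell cycle genes kept 75.6% (70.1% and 81.1% from the single 22-B3 libraries), acute phase genes 73.1% (77.6% and 68.4%) and chaperone genes 67.9% (56.2% and 79.5%). Fucosylation genes kept 40.7% (47.8% and 33.8%) and STAT3 feedback genes 25.4% (36.4% and 14.3%). Ratios of list means can rest on a few genes. The median log2 change of the fucosylation list was 0.37 with WT IL-22 and 0.29 with 22-B3. That of the STAT3 feedback list was 0.65 and 0.14. Cholesterol synthesis genes kept 93.6% (127.1% and 60.1%), MHC class II genes 94.2% (63.3% and 125%), macrophage genes 59.2% (48.2% and 70%), smooth muscle genes 49% (68.9% and 29.1%) and glucocorticoid response genes 45.2% (55.6% and 34.8%).

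Of the 148 genes that rose with 22-B3, 146 rose with WT IL-22, and of the 24 that fell 23 fell. Ighv1-54, named here after its values were seen, rose with 22-B3 and fell with WT IL-22. Unchanged groups simulated against shared PBS libraries drawn anew had a mean of 0.18 rises and 0.12 falls in common. If both PBS libraries came from 1 animal these were 1.52 and 0.42, with at most 9 and 3 in a draw. With the PBS libraries summed, 2 of 2 rises and 3 of 3 falls were shared, as without PBS replicate 2, and 7 of 7 and 3 of 3 without PBS replicate 1. The shared calls were 96 of 100 and 22 of 37 without WT IL-22 replicate 1, 203 of 215 and 48 of 62 without 22-B3 replicate 1, and 1242 of 1391 and 738 of 858 without 22-B3 replicate 2. The log2 changes of the 2 treatments correlated at 0.778 across genes, which are not independent replicates, with a covariance of 0.262, and 82.4% of the genes tested had the same sign in both. The simulated groups gave 0.501, 0.0655 and 66.7%, or 0.649, 0.121 and 72.9% with 1 PBS animal. The 2 PBS libraries cannot be split into 2 control groups, so part of the excess may come from the shared controls.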

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

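The alternatives with PBS libraries summed, without immunoglobulin variable genes and without Yam1, Lars2 and Gm26917 were chosen after the data had been seen. Counts are given as genes higher and lower, for WT IL-22 against PBS, 22-B3 against PBS and 22-B3 against WT IL-22 in that order, and stood at 1547 and 1054, 148 and 24, and 5 and 11. Over the alternatives, 12186 results of named genes stayed on their side of the threshold, 453 passed newly, 711 no longer passed and 0 reversed. Of the list results 3012 stayed on their side, 69 passed newly, 136 no longer passed and 2 reversed. Staying on a side includes staying short of the threshold. In the main fit 122 of 207, 34 of 206 and 15 of 201 named genes had passed, for the comparisons in that order, and only these could be lost. A reversal was counted only where the result passed in the main fit or in the alternative. Results that passed in neither may have changed direction. The 2 that reversed were B and plasma cell genes (camera adjusted p = 0.0445) and cholesterol synthesis genes (camera adjusted p = 0.0465), upward in 22-B3 against WT IL-22 without 22-B3 replicate 2 and downward with all libraries (camera adjusted p = 0.413 and 0.938). With 1 library left out these ran from 0.000151 to 0.839 and from 0.0465 to 0.926. PBS libraries summed gave 129 and 29, 2 and 3, and 2 and 2, with 1 residual degree of freedom fewer. Fitting the 4 libraries compared gave 2778 and 2248, 38 lower for 22-B3 against PBS, and 2 and 2 for 22-B3 against WT IL-22. With no low-count filter 22-B3 gave 353 and 78 against PBS and 36 and 65 against WT IL-22, and the correlation of the changes was 0.694. DESeq2 gave 550 and 141 for 22-B3 against PBS and 77 and 110 for 22-B3 against WT IL-22. On log2 FPKM with no filter the counts were 708 and 360, 27 and 11, and 1 and 1, with 9 lists for 22-B3 against PBS. With a pseudocount of 0.1 on FPKM, 2 genes were higher in 22-B3 than WT IL-22 and 9 lists passed for 22-B3 against PBS, and 9 lists passed with CPM above 1 in 2 libraries. Upper-quartile scaling left 93 genes higher for 22-B3 against PBS, and without immunoglobulin variable genes 2 were higher in 22-B3 than WT IL-22. At an adjusted p under 0.01 the counts were 431 and 140, 45 and 7, and 1 and 2, and at least a 2-fold change left 525 and 360 for WT IL-22. Lists passed 11, 14 and 10 times with camera, 0, 0 and 0 times with an estimated correlation and 4, 1 and 0 times with fry. Over genes that passed for 22-B3 in place of WT IL-22 the share kept was 76.6%. The causes were not tested, apart from the smaller sets of libraries and stricter thresholds.

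With 1 library left out, the count of genes higher ran from 117 to 2782 and lower from 28 to 2454 for WT IL-22 against PBS, 2 to 1391 and 3 to 858 for 22-B3 against PBS, and 2 to 435 and 2 to 201 for 22-B3 against WT IL-22. The lowest values came without a PBS library (for genes higher in 22-B3 than WT IL-22 also without WT IL-22 replicate 1) and the highest without a 22-B3 library, where the remaining library of a group is assumed to vary like the others. Lists passed 11 to 15, 6 to 18 and 8 to 14 times, the share kept ran from 52.3% to 66.8% and the correlation from 0.614 to 0.802. The replicate block gave 2496 and 2008, 787 and 276, and 71 and 112. Deviations of same-numbered libraries correlated at 0.0369 for PBS and WT IL-22, 0.0399 for PBS and 22-B3 and 0.209 for WT IL-22 and 22-B3, so the numbers were not taken to pair the libraries. The correlation of changes rests on no test, so it has no value under DESeq2, voom, the replicate block, the 4 libraries or the summed PBS libraries. Some genes had counts near the floor, such as Prss27, Saa2, S100a8 and Il6, and whether more depth would change their results was not tested.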

Other observations

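The tests of explanations below were chosen after the results had been seen, except that of a pool of several animals, whose bounds were set beforehand.

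Several further lists did not pass with WT IL-22 but held genes that passed, in some of them both ways. Among circadian clock genes (camera adjusted p = 0.675) Npas2 stood at 1.21 and Ciart at -0.82 on the log2 scale (edgeR adjusted p = 0.00841 and 0.0142). Of 16 p53 targets 3 fell, among them the apoptosis gene Bbc3 at -1.24, and 1 rose, Aen at 0.75 (edgeR adjusted p = 0.00933 and 0.0135). Adjusted over the list alone 4 fell and 1 rose, and 13 of 16 were lower whether or not they passed (camera adjusted p = 0.12). Hk2, a hexokinase, rose by 1.59 while Ankrd37 and Bnip3 stood at -2.59 and -0.94 (edgeR adjusted p = 0.00834, 0.00835 and 0.00994). Among transporters the sodium channel subunit Scnn1g fell, at -1.61, and the sodium-proton exchanger Slc9a3 rose by 1.18 (edgeR adjusted p = 0.00794 and 0.0107), and the zinc transporter Slc39a10 rose by 1.69 (edgeR adjusted p = 0.00213). In the goblet cell list Tff3 and Spink4 fell, at -1.31 and -0.98 (edgeR adjusted p = 0.00613 and 0.0246). The distal colon genes Hoxb13 and Hoxd11 stood at -0.58 and -1.09 (edgeR adjusted p = 0.0455 and 0.0377). Relative to PBS, the distal colon list stood at -0.88 and -0.31 in the WT IL-22 libraries (camera adjusted p = 0.214). The proximal colon list stood at 0.64 and -0.30 (camera adjusted p = 0.812). Whether the pieces came from the same part of the colon was not tested, which limits the reading of genes that differ along it. With the PBS libraries summed edgeR called 0 circadian, p53, goblet cell and distal colon genes (5, 4, 2 and 2 at an unadjusted p under 0.05).

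The PBS libraries were closer than any other pair. That they are 1 library deposited under both names is argued against by 24.7% of genes beyond the 5% point of chi-square. Their correlation of variable gene counts (0.963, no other pair above 0.165) is consistent with RNA of 1 animal. A single pool of more animals than in a treated library is argued against by an effective number of 55.8 variable genes in both PBS libraries. That lies within the 47.7 to 62.3 of the treated libraries, the range set beforehand. It is also below the 62.9 to 72.7 of equal mixtures of 2 of them, a comparison not set beforehand. The bound set in favour of a pool was 93.4, above the 79.2 of all treated libraries mixed, so the test could not have favoured a pool. The labels also do not state that a treated library came from 1 animal. With RNA of 1 animal the PBS spread may be too small. Unchanged groups simulated against 1 PBS animal gave a mean of 5.9 calls among 15628 genes over 10 draws, against 1 with 2 animals. Each gene was drawn on its own there. The draws therefore cannot show how many calls an animal with many genes shifted together would give.

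Immunoglobulin variable genes were among the strongest changes, with 15 rises and 20 falls among 137 tested for WT IL-22 against PBS, 4 and 7 with the PBS libraries summed or without PBS replicate 1, 2 and 7 without PBS replicate 2, and 26 and 33 without either 22-B3 library. A change in the number of B or plasma cells would tend to move them 1 way, and 57.1% of those that passed went the more common way. In the B and plasma cell list 10 of 11 genes were lower with WT IL-22, with a median log2 change of -0.56. Variable genes differed by more than that between libraries of a group, so the split cannot decide on a change in cell number. The median absolute log2 ratio of these genes between libraries of a group was 1.73 for WT IL-22 and 2.03 for 22-B3, as antibody genes that differ between single animals would give. That may also account for the change between groups, with an effect of treatment on single clones untested.

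The share of the WT IL-22 change kept by 22-B3 was higher in the cell cycle list than in the STAT3 feedback list. The gap was 33.7 points in 22-B3 replicate 1 and 66.8 in replicate 2. These lists were picked after the shares had been seen, and the difference between them was not tested. Less epithelium in the 22-B3 tissue is argued against by 10 epithelial genes, whose median change from WT IL-22 was 0.13 log2 (SD 0.209) against -0.41 for the STAT3 feedback genes. A PBS animal low in cell cycle genes stays open: it would need a shift of 0.65 log2, more than the 0.106 between libraries of a treated group, and the PBS pair cannot show how animals vary. A lower signal to which genes respond at different strengths is a candidate explanation that 1 dose and 1 time leave untested.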
